A study of Mus musculus with 4 samples.

How the data were processed

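Messenger RNA was measured in stromal cells sorted from the whole large intestine of mice. The sort kept living cells (7AAD-negative) that carried podoplanin, a surface protein of fibroblasts and lymphatic endothelium. It left out cells with CD45 (leukocytes), CD31 (endothelium) or EpCAM (epithelium). The series holds 4 libraries in 4 groups, with 1 library per group: BALB/c wild type, BALB/c Rag2 knockout, C57BL/6J wild type and C57BL/6J IL-10 knockout. Per the labels, total RNA was extracted with a miRNeasy kit and libraries were made with the TruSeq stranded mRNA kit. The labels do not say how many animals went into each library.

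The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), computed by the authors, with 1 value per gene symbol. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18, Cuffdiff 2.2.1 and the mouse build mm10. The gene annotation, the strand setting of counting and the library normalization of Cuffdiff are not given in the sources used here. Each file lists 23284 gene symbols, and 0 symbols were repeated. FPKM of very short transcripts are inflated by the division by length: 777 rows of small RNAs held between 8.90% and 14.8% of the FPKM sum of a library, and the top row of every library was the microRNA gene Mir682. Because whole-gene FPKM carry no exon information, a deletion of part of a gene cannot be seen in them.

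Fragment counts were not used here. The depth was estimated from the steps between the lowest FPKM values of transcripts of at least 1000 nt, which correspond to whole fragments. A line with a length offset of 200.4 nt placed 117 of the 180 genes used within 5% of it. The estimate was about 9892000 fragments for BALB/c wild type, 9618000 for BALB/c Rag2 knockout, 8673000 for C57BL/6J wild type and 8330000 for C57BL/6J IL-10 knockout, a range of 1.19-fold. At the lowest of these depths and for a transcript of 2000 nt, an FPKM of 1 stands for about 15 fragments. For a pair of such values, the log2 ratio of the FPKM themselves, with nothing added, has a 95% interval of 1.13 on either side. An FPKM of 5 stands for about 75 fragments (0.48 on either side) and an FPKM of 50 for about 750 fragments (0.15 on either side). A count of 3 fragments corresponds to 0.200 FPKM. These intervals cover counting error only, since fragments copied by PCR are not independent molecules.

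Values were transformed as log2 of FPKM plus a pseudocount of 1, and the difference between a pair of libraries is called the log2 ratio. Genes with an FPKM of at least 1 in either library were compared, and genes at least 2-fold apart (an absolute log2 ratio of at least 1) were counted. With 1 library per group there is no replicate error, so no p-value, standard error or test between groups was computed, and "higher" and "lower" describe these libraries. The comparisons were IL-10 knockout against C57BL/6J wild type, Rag2 knockout against BALB/c wild type, and BALB/c wild type against C57BL/6J wild type. The log2 ratio of the Rag2 comparison was also subtracted from that of the IL-10 comparison, gene by gene. Those knockout comparisons share no library, whereas the comparison of the wild types shares a library with each of them.

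Before the data were examined, 41 gene lists were fixed. They cover pathways, stromal cell states and reference genes, and 14 of them hold markers of cell types. Of their 741 members, 715 were found in the files. Immunoglobulin and T cell receptor constant genes, Muc2, Ly6g and Foxf1 were among those not found and are not used here. For each list the median log2 ratio of its measured members was computed, with a 95% bootstrap interval over members (10000 draws; members are genes, not replicates). Its percentile was taken among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these libraries. Some lists share members, among them 7 genes of the epithelial niche factor and PDGFRA-high fibroblast lists and 6 genes of the collagen and fibroblast marker lists. Neither interferon list shares a member with the other or with the lists of leukocyte markers.

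Named genes were chosen by a rule fixed at the same time. Genes needed an FPKM of at least 5 in the higher library and an established symbol. Small RNAs, predicted or clone names, pseudogene symbols ending in -ps, and immunoglobulin or T cell receptor segments were left out. Of the rest, those with the 12 highest and the 12 lowest ratios were named in each knockout comparison. Between the wild types 8 and 8 were named, and 6 and 6 for the difference between knockouts. Genes of the IL-10, recombinase and interferon pathways, the sort markers, and up to 4 members of each list with the largest absolute ratio were added. Genes named outside that rule are said to have been chosen after their values were seen. Positions were taken from the RefSeq annotation of the same build.

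The counting was tested on a simulated IL-10 comparison, with fragments drawn at depths of 8696000 (wild type) and 8333000 (knockout) and 200 genes given a known change. Of the 12048 simulated genes that passed the filter, 196 were seeded, 49 at each fold. Among the seeded genes, 2.04% were called at a true fold of 1.5, 34.7% at 2, 85.7% at 3 and 93.9% at 4. Counting noise alone carried 34 of 11852 unchanged genes past 2-fold. The computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Alternatives fixed with the lists were pseudocounts of 0.1 and 5, no expression filter, a filter of 5 FPKM, rescaling of each library to a sum of 1000000 or by the median of ratios, a threshold of 4-fold, and lists without shared members. Added after seeing the data were counts without small RNA rows, counts of genes whose counting interval leaves out 0, and counts of genes 2-fold apart from both wild types or between all pairs of BALB/c and C57BL/6J libraries. The reads were not used here, so neither mapping nor genetic variants were analysed.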

Results

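The data are FPKM values of 4 RNA sequencing libraries from podoplanin-positive stromal cells of the mouse large intestine, sorted without leukocytes, endothelium and epithelium. BALB/c wild type, BALB/c Rag2 knockout, C57BL/6J wild type and C57BL/6J IL-10 knockout each have 1 library, so no value below has a replicate error. The estimated depth was about 9892000 fragments in BALB/c wild type, 9618000 in the Rag2 knockout, 8673000 in C57BL/6J wild type and 8330000 in the IL-10 knockout. Genes with an FPKM of at least 1 numbered 11869, 11823, 11808 and 12301 in the same order. In a comparison, "higher" and "lower" mean at least 2-fold apart in log2 of FPKM plus 1 where counts of genes are given, and otherwise describe the values shown.

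The gene of the sort marker was expressed in all 4 libraries, which does not show that they held stromal cells alone. Pdpn, which encodes the podoplanin used for sorting (chromosome 4, 143267409 to 143299564 in GRCm38/mm10), had 189.6 FPKM in BALB/c wild type, 292.5 in the Rag2 knockout, 158 in C57BL/6J wild type and 204 in the IL-10 knockout. Transcripts of the sort markers for the cells that the gate leaves out were lower than Pdpn but not absent, and they differed between libraries. Ptprc, which encodes CD45, had 8.31 FPKM in BALB/c wild type, 11.5 in the Rag2 knockout, 3.34 in C57BL/6J wild type and 43.1 in the IL-10 knockout. For Epcam the values were 2.76, 9.35, 6.29 and 21.1 FPKM in the same order, and for Pecam1, which encodes CD31, they were 13.3, 13.3, 12.4 and 17.9 FPKM.

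Transcripts of the deleted genes were looked at first. Il10 (chromosome 1, 131019845 to 131024970) had 3.33 FPKM in C57BL/6J wild type and 129.9 FPKM in the library labelled IL-10 knockout, a log2 ratio of 4.92. In BALB/c it had 3.38 FPKM in wild type and 7.04 FPKM in the Rag2 knockout. The Il10 value adds up all fragments of the gene and does not show whether the deleted part was present. Rag2 (chromosome 2, 101624712 to 101632528), which encodes a subunit of the recombinase that assembles antigen receptor genes, was listed at 0 in BALB/c wild type and in both C57BL/6J libraries and at 0.710 FPKM in the Rag2 knockout, so it gives no check of that label. Genes of B cells give one: Igj, the joining chain of antibodies, had 428 FPKM in BALB/c wild type and 1.36 in the library labelled Rag2 knockout.

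Sex-linked transcripts differed between the libraries. Xist, the RNA of the inactive X chromosome, had 0.0509 FPKM in BALB/c wild type, 0.105 in the Rag2 knockout, 23.02 in C57BL/6J wild type and 44.9 in the IL-10 knockout. The Y-linked helicase gene Ddx3y had 36.3, 31.5, 16.9 and 0.0269 FPKM in the same order. C57BL/6J wild type thus held transcripts of both kinds, and sex-linked genes separate the C57BL/6J libraries from each other as well as from the BALB/c libraries. The fixed list of 5 sex-linked genes had a median log2 ratio of -1.74 in the IL-10 comparison and -0.19 in the Rag2 comparison.

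**Figure D1:**
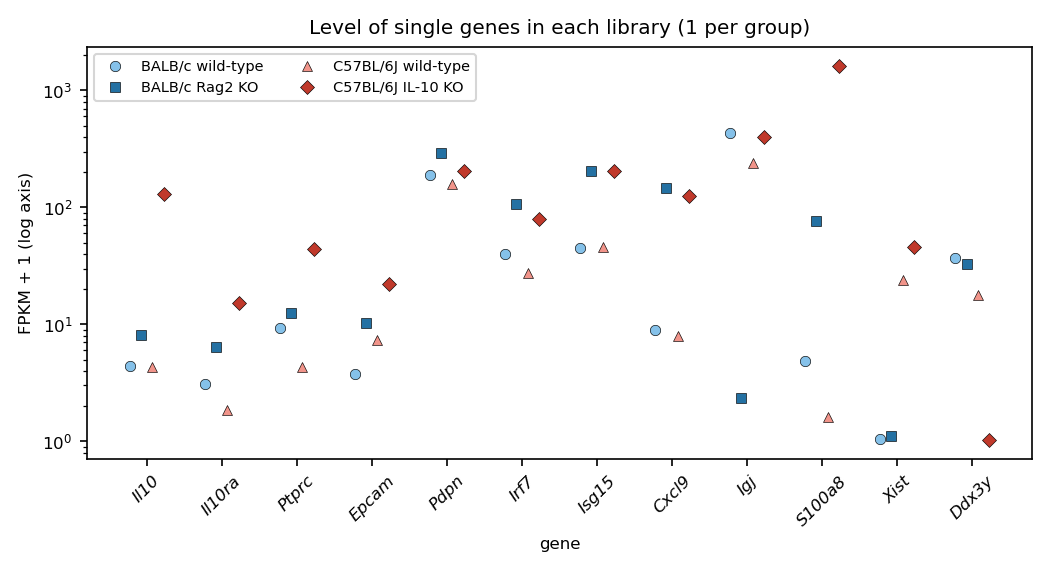
FPKM plus 1 on a log axis of 12 genes (pathway genes, sort markers, interferon-induced, inflammatory, B cell and sex-linked genes) in the 4 libraries, with 1 point per library. Il10 stands at 129.9 FPKM in the library labelled IL-10 knockout and at 7.04 FPKM or less in the other libraries, and Isg15 stands at 206 and 203 FPKM in the knockout libraries against 44.4 and 43.9 in the wild types.

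The comparison of the IL-10 knockout with C57BL/6J wild type addresses how colonic stromal cells differ in mice labelled as lacking IL-10, a cytokine that restrains inflammation, and in particular their interferon response. Interferon-induced, antigen presentation, inflammatory and complement genes were higher in the IL-10 knockout library, and smooth muscle and PDGFRA-high fibroblast genes were lower. Zbp1, which encodes a sensor of nucleic acids, had 77.6 FPKM against 4.86 in wild type (log2 ratio 3.75). S100a8 and S100a9, subunits of calprotectin, a protein abundant in neutrophils, reached 1624 and 1833 FPKM against 0.621 and 3.27. Markers of leukocytes were higher as well: all 12 measured pan-haematopoietic genes were at least 2-fold higher, with a median log2 ratio of 2.996.

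In all, 1297 of 12790 genes were at least 2-fold higher and 488 at least 2-fold lower in the IL-10 knockout, and at a threshold of 4-fold the counts were 478 and 62. The rankings below cover genes that meet the naming rule, which leaves out small RNAs. The genes with the highest ratios were S100a8 (9.97), Chi3l1 (9.36), S100a9 (8.75), the haptoglobin gene Hp (6.97), the antimicrobial lectin gene Reg3b (6.96), the serum amyloid gene Saa3 (6.73), the lipocalin gene Lcn2 (6.15), Irg1 (5.90), the neutrophil gene Retnlg (5.54) and Retnlb (5.29). Reg3g and Ngp had 59.1 and 43.5 FPKM in the knockout and were listed at 0 in wild type. The lowest ratios were those of Ddx3y (-4.13), Plac9 (-4.04), Sycn (-3.83), Stmn2 (-3.74), Hapln1 (-3.40), the calsequestrin gene Casq2 (-3.38), Aldh3a1 (-3.22), Rerg (-3.07), Col4a6 (-2.86), Arhgap22 (-2.85) and Ccdc3 (-2.80). Eif2s3y, on the Y chromosome, had 9.22 FPKM in wild type and was listed at 0 in the knockout. Plac9, Sycn and Col4a6 were low in both BALB/c libraries as well (0, 2.87 and 1.77 FPKM in BALB/c wild type). C57BL/6J wild type had 23.5, 27.9 and 24.3 FPKM, so these ratios rest on high values in that library alone.

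Of the 42 measured type I interferon-stimulated genes, 28 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.21 (95% bootstrap interval over members 1.004 to 1.480). Ifit1, which binds viral RNA, had 24.6 FPKM against 4.38 in wild type (2.25). Isg15 (chromosome 4, 156199424 to 156200818), a ubiquitin-like protein gene, had 206 against 44.4 FPKM (2.18), and Irf7 (chromosome 7, 141263183 to 141266499), a transcription factor that amplifies type I interferon, had 78.8 against 26.6 (1.53). Genes of the interferon-gamma type stood further apart: 24 of 27 were at least 2-fold higher and 0 lower, with a median of 2.15 (1.78 to 2.71). The T cell chemokine gene Cxcl9 (chromosome 5, 92321331 to 92328079) had 123 against 6.91 FPKM (3.97), the GTPase gene Gbp2 had 311.8 against 29.4 (3.36), and Nlrc5, an activator of MHC class I genes, had 21.0 against 1.24 (3.30). Among 19 interferon ligand, receptor and sensor genes the median was 0.74 and 5 were at least 2-fold higher. Ifng had 11.7 against 0.114 FPKM, whereas Ifnb1 was listed at 0 in wild type and had 0.21 FPKM in the knockout. The type I receptor genes Ifnar1 and Ifnar2 had 17.6 and 121 FPKM against 11.1 and 71.0.

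MHC class II genes were higher as a group, with all 11 at least 2-fold apart and a median of 2.87. The invariant chain gene Cd74 had 1595 against 191 FPKM (3.05), and H2-Ab1 had 811 against 101 FPKM (2.99). Of 20 genes of MHC class I presentation 13 were at least 2-fold higher (median 1.23), among them B2m, the light chain of class I molecules, with 7098 against 1548 FPKM (2.197) and the peptide transporter gene Tap1 with 112 against 17.5 (2.61). Inflammatory cytokines and chemokines had a median of 1.83, with 23 of 30 higher. Saa3 (chromosome 7, 46711998 to 46719615) had 1538 against 13.5 FPKM, and the neutrophil chemokine gene Cxcl5 had 110 against 4.90 (4.24). NF-kappaB feedback and adhesion genes had a median of 0.86 (7 of 18 higher), and complement genes one of 1.14 (8 of 13 higher), with Cfb at 493 against 34.3 FPKM (3.81) and C3 at 6299 against 723 (3.12). In the IL-10 receptor and STAT3 list the median was 0.51 and 3 of 15 genes were higher: Il10 itself, Il10ra, the receptor chain gene (chromosome 9, 45253837 to 45269149; 14.1 against 0.835 FPKM), and Il22 (15.3 against 1.43 FPKM). Il10rb had 45.4 against 30.6 FPKM (0.56).

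Beside these groups, markers of other cell types were higher in the IL-10 knockout library. Medians were 2.56 for T cells and innate lymphoid cells (12 of 14 at least 2-fold higher), 2.26 for B and plasma cells (8 of 10), 2.33 for macrophages and monocytes (15 of 17) and 4.03 for neutrophils and mast cells (9 of 10). Tyrobp, an adaptor of myeloid cells, had 228 against 12.8 FPKM, and the B cell gene Ms4a1 had 9.53 against 0.556. Epithelial markers had a median of 1.64 with 17 of 19 higher, among them Tff3, a peptide of goblet cells, at 88.6 against 11.4 FPKM. The mesothelial list had a median of 1.82 (4 of 5 higher), but it includes C3, which the complement list holds too. Blood endothelial markers had a median of 0.02 and the 17 fibroblast markers one of 0.00, while lymphatic endothelium had -0.51, interstitial cells of Cajal -0.82, adipocytes -0.27 and enteric glia and neurons 0.02. Too few erythroid genes were measured for a list, and Hba-a1, a haemoglobin gene, had 186.5 FPKM against 34.2.

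Smooth muscle and myofibroblast genes were lower as a group, with 10 of 14 at least 2-fold lower, 0 higher and a median of -1.10 (-1.29 to -0.97). Myh11, the myosin heavy chain of smooth muscle, had 23.4 against 69.8 FPKM (-1.54), and Hhip, an antagonist of hedgehog ligands, had 4.33 against 18.5 (-1.87). Of 15 genes of PDGFRA-high fibroblasts, which lie under the epithelium, 11 were at least 2-fold lower and 0 higher (median -1.59). Enho had 9.17 against 63.8 FPKM (-2.67), the endothelin receptor gene Ednrb 1.62 against 15.4 (-2.64) and the BMP ligand gene Bmp5 27.2 against 159.8 (-2.51). Epithelial niche factors went both ways, with 8 of 29 higher and 10 lower. The R-spondin gene Rspo1 had 17.35 against 3.66 FPKM (1.98) and Wnt4 had 6.45 against 34.1 (-2.24). Their median was -0.44, and it was 0.15 without the genes that other lists also hold. Collagen and matrix genes had a median of -0.38 with an interval that holds 0 (-0.59 to 0.01), and 22 of 30 were within 2-fold, 7 lower and 1 higher, with Postn at 385 against 1544 FPKM (-2.001) and Col12a1 at 22.8 against 96.8 (-2.04). Basement membrane genes had a median of -0.42, pericyte genes -0.47 and retinoid genes -0.61, the last with the retinaldehyde dehydrogenase gene Aldh1a1 at 20.2 against 85.7 FPKM (-2.03).

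Adventitial fibroblast genes had a median of 0.64 with 8 of 17 higher, including Pi16 at 502.7 against 75.4 FPKM (2.72). Lymphoid stromal genes had a median of 0.37, matrix-degrading enzymes and inhibitors 0.14, hypoxia and glycolysis genes 0.32, the unfolded protein response 0.14, cholesterol synthesis 0.01 and dissociation-related immediate early genes -0.22. Cell cycle genes, of which 8 of 18 were higher, had a median of 0.77, with Mki67 at 4.40 against 0.521 FPKM. Housekeeping genes stood at 0.23 and ribosomal protein genes at -0.07. The housekeeping genes Gapdh and Ppia, named after their values were seen, were near 0 in all 4 libraries (Gapdh 0.196 to 0.349 FPKM, Ppia 0.433 FPKM or less) and did not pass the filter, so a gene near 0 or listed at 0 in these files need not be silent. Across the 40 lists that could be scored, 20 medians lay above the middle 95% of their random matched lists and 11 below it. For lists of unrelated genes 1 would be expected on each side, but members of a fixed list can move together. The comparison of the wild types gave 10 and 8, so these counts only describe the libraries. With a pseudocount of 5 the genes at least 2-fold higher and lower numbered 611 and 182. Sex, genotype and individual animals cannot be separated in this comparison, because each group has 1 library.

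The comparison of the Rag2 knockout with BALB/c wild type addresses the same cells in mice labelled as lacking Rag2, without which T and B cells do not mature. B cell genes were lower and interferon-induced, inflammatory and complement genes higher in the Rag2 knockout library. Cd79a, a signalling chain of the B cell receptor, had 0.829 FPKM against 11.4 in wild type (log2 ratio -2.76), and Igj had a ratio of -7.50. Zbp1 had 109 against 7.14 FPKM (3.76), Saa3 had 1013 against 12.1 (6.27), and Cxcl9 had 145 against 7.92 (4.04).

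In all, 545 of 12336 genes were at least 2-fold higher and 251 at least 2-fold lower in the Rag2 knockout. At 4-fold the counts were 150 and 34. As before, the rankings cover genes that meet the naming rule, which leaves out small RNAs. The highest ratios were those of Reg3b (6.48), Saa3 (6.27), Reg3g (5.45), Apol6 (4.83), the GTPase gene Gbp4 (4.61), Chl1 (4.50), Irg1 (4.13), Cxcl9 (4.04), S100a9 (4.03), H2-Q7 (4.004) and S100a8 (3.98), and Pla2g2a had 40.004 FPKM where wild type was listed at 0. Among the lowest after Igj were Cd79a and Cd79b (-2.48), which encode the signalling chains of the B cell receptor, Casq2 (-2.18), the T cell gene Cd2 (-2.14), Emid1 (-2.06), Hhip (-1.94), Gimap3 (-1.93) and the fatty acid transporter gene Cd36 (-1.93). Pou2af1, a coactivator of B cells, and Snhg9 had 8.12 and 5.74 FPKM in wild type and were listed at 0 in the knockout.

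Type I interferon-stimulated genes had a median of 1.35 (0.98 to 1.69), with 26 of 42 at least 2-fold higher and 0 lower. Oas2, a sensor of double-stranded RNA, had 8.26 against 0.411 FPKM (2.71), Isg15 203 against 43.9 (2.19) and Irf7 107 against 38.8 (1.43). The interferon-gamma-type list had a median of 2.36 (1.957 to 2.677) and 22 of 27 genes higher, including Gbp4 at 224 against 8.22 FPKM (4.61). For interferon ligands, receptors and sensors the median was 0.27, with Ifng at 3.61 against 0.301 FPKM (1.83) and Ifnb1 at 0.18 FPKM where wild type was listed at 0. MHC class I presentation had a median of 1.69 (18 of 20 higher), with the immunoproteasome gene Psmb8 at 232.5 against 41.7 FPKM (2.45). MHC class II genes had a median of 0.69: 3 of 10 were at least 2-fold higher, among them H2-DMa (1.499), and 2 were lower, among them H2-Ob (-1.88), which B cells express. Inflammatory genes had a median of 1.85 (22 of 29 higher), NF-kappaB feedback and adhesion genes 0.63 with Vcam1 at 263 against 75.1 FPKM (1.80), and complement genes 1.21 with Cfb at 439.9 against 32.3 (3.73) and C7 at 88.9 against 9.22 (3.14). In the IL-10 receptor and STAT3 list the median was 0.21, and Il22 (2.70) and Il10ra (1.05) passed 2-fold.

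The marker lists of leukocytes diverged in the Rag2 knockout library. B and plasma cell markers had a median of -2.20 with all 10 at least 2-fold lower, and T cell and innate lymphoid markers one of -0.62 with 4 of 12 lower and 1 higher. The pan-haematopoietic median was 0.40, macrophage markers had 0.64 (7 of 18 higher) and neutrophil and mast cell markers 1.29 (5 of 8 higher), with S100a9 at 121 against 6.45 FPKM. Beside the interferon and inflammatory groups, epithelial markers were higher, with a median of 1.52 and 15 of 19 at least 2-fold higher, among them the keratin gene Krt19 (2.27) and Tff3 at 20.2 against 1.60 FPKM. The mesothelial median was 2.27 (4 of 5 higher, C3 and Krt19 included). Fibroblast markers had a median of 0.03, blood endothelium -0.02, lymphatic endothelium -0.55, interstitial cells of Cajal -0.51, glia and neurons -0.08 and adipocytes -0.03.

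Smooth muscle and myofibroblast genes were again lower, with 7 of 14 at least 2-fold lower, 0 higher and a median of -0.97. Myh11 had 32.3 against 93.7 FPKM (-1.51) and Myl9, the regulatory light chain of myosin, 111 against 258 (-1.21). PDGFRA-high fibroblast genes had a median of -0.78 with 4 of 15 lower, among them Bmp5 at 58.2 against 118 FPKM (-1.01). Collagen and matrix genes had a median of -0.13, basement membrane genes -0.04, pericyte genes -0.46 and retinoid genes -0.01, although Aldh1a1 had 30.1 against 98.6 FPKM (-1.68). Niche factors had a median of 0.10, and the BMP inhibitor gene Grem1 had 197 against 84.3 FPKM (1.21). The adventitial list had a median of 0.34, with Ly6a, which encodes SCA-1, at 2894 against 475 FPKM (2.61) and Ly6c1 at 882 against 141 (2.64). Matrix-degrading enzymes and inhibitors had 0.38, with Mmp3 (2.97), Timp1 (2.17) and Timp3 (1.54) among the 5 of 20 that were higher. Medians of 0.57 for the unfolded protein response, 0.55 for cholesterol synthesis, 0.34 for lymphoid stromal genes, 0.26 for hypoxia and glycolysis, 0.12 for immediate early genes and 0.02 for the cell cycle were also found, against 0.22 for housekeeping and -0.32 for ribosomal protein genes.

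Of the 40 list medians, 19 lay above the middle 95% of random matched lists and 9 below it, as a description of these libraries. Of the genes at least 2-fold apart 68.5% were higher in the Rag2 knockout, and 58.4% were once each library was rescaled to a sum of 1000000. With a pseudocount of 5 the counts of higher and lower genes were 278 and 68.

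The knockout comparisons share no library, and their difference asks which genes stood further apart in the comparison labelled IL-10 knockout than in the Rag2 comparison, although strain, sex and genotype cannot be separated in it. Interferon-induced genes had similar ratios in both: the difference of the log2 ratios had a median of -0.04 over the type I list and 0.11 over the interferon-gamma-type list. Leukocyte genes were not. Medians were 4.71 for B and plasma cell markers, 3.09 for T cells and innate lymphoid cells, 2.58 for pan-haematopoietic genes, 2.43 for neutrophils and mast cells and 1.68 for macrophages. MHC class II genes had a median difference of 2.30, with all 11 members at least 2-fold apart, led by H2-Ob (4.58).

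Across the 12048 genes expressed in both comparisons, the log2 ratios correlated with a Pearson r of 0.557, a Spearman rho of 0.479 and a covariance of 0.308, across genes, which are not independent replicates. Genes at least 2-fold higher in both knockouts numbered 397, where 44.8 would be expected if the sets were independent, and 105 were lower in both, where 8.40 would be expected. Another 43 were higher in the IL-10 and lower in the Rag2 knockout, with B and T cell genes such as Cd79a, Cd2 and Cd3g among them. The 3 genes that went the other way, Snord32a, Mir719 and Snora31, are small RNAs; they were named after their values were seen.

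By the difference itself, 952 of 13078 genes had a log2 ratio at least 1 higher in the IL-10 comparison and 338 at least 1 lower. Genes ranked next meet the naming rule, which leaves out small RNAs. Among the largest differences were those of Chi3l1 (8.38), Igj (8.24), S100a8 (5.99), Pou2af1 (5.51) and Ngp (5.47), and at the other end of Plac9 (-4.04), Ddx3y (-3.93), H2-Q10 (-3.82), Sycn (-3.35), Eif2s3y (-3.18) and Inmt (-2.94). Plac9 was listed at 0 in both BALB/c libraries, so its difference rests on the C57BL/6J libraries. PDGFRA-high fibroblast genes had a median difference of -0.88, with Wnt4 (-2.29) and Enho (-1.86) lowest, cell cycle genes one of 0.80, basement membrane genes -0.43 and collagen genes -0.32. Smooth muscle genes had -0.11 and epithelial markers 0.29. Of 40 lists, 13 medians lay above the middle 95% of random matched lists and 10 below it. A pseudocount of 5 gave 393 and 130 genes.

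**Figure D2:**
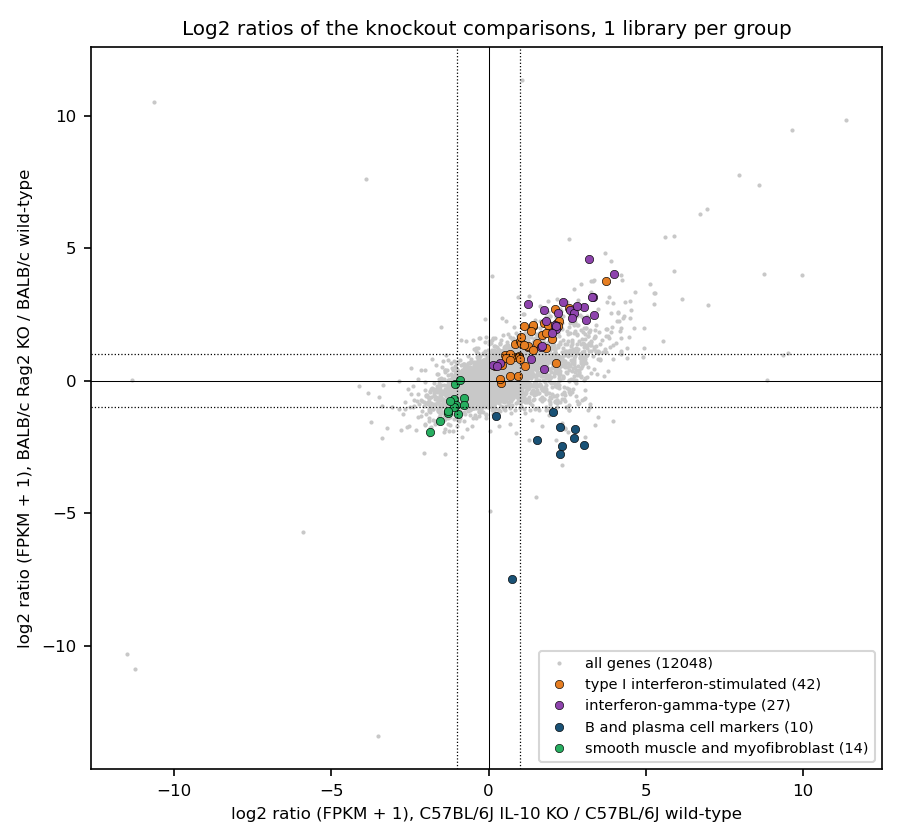
Log2 ratio of IL-10 knockout over C57BL/6J wild type (x axis) against log2 ratio of Rag2 knockout over BALB/c wild type (y axis) for 12048 genes, with genes of 4 fixed lists coloured and dotted lines at 1 and -1. Type I and interferon-gamma-type genes lie high on both axes (medians 1.21 and 1.35, 2.15 and 2.36), smooth muscle genes low on both, and B and plasma cell markers high on the x axis and low on the y axis (2.26 and -2.20).

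The comparison of the wild types serves as background for the knockouts. Ribosomal protein genes stood out singly, and cholesterol synthesis and epithelial genes as groups, as lower in BALB/c wild type. Both groups were higher in the Rag2 knockout than in BALB/c wild type (medians 0.55 and 1.52). Epithelial markers were also higher in the IL-10 knockout than in C57BL/6J wild type (1.64), whereas cholesterol synthesis genes were not (0.01). With 1 library per group, a strain trait cannot be told apart from a trait of the BALB/c wild-type library alone. Rps18, a protein of the small ribosomal subunit (chromosome 17, 33951998 to 33955665), had 0.635 FPKM in BALB/c against 156 in C57BL/6J, and values of 0.326 and 146 in the knockouts of the same strains. Among cholesterol synthesis genes 6 of 16 were at least 2-fold lower and 0 higher, with a median of -0.77 (-1.20 to -0.63). Fdps, an enzyme of isoprenoid synthesis, had 1.83 against 8.93 FPKM (-1.81), and Sc5d, an enzyme of sterol synthesis, 4.27 against 13.4 (-1.45). The type I interferon list had a median of -0.03, with 0 of 38 genes 2-fold apart. The interferon-gamma-type list had a median of 0.41 (0.10 to 0.68), above the middle 95% of random matched lists, with 19 of 24 genes higher in BALB/c by any amount, 1 at least 2-fold higher and 2 at least 2-fold lower.

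In all, 223 of 12290 genes were at least 2-fold higher and 267 lower in BALB/c, and 41 and 47 at 4-fold. Rankings here again follow the naming rule, which leaves out pseudogene symbols such as H2-Ea-ps (7.58). The highest ratios were those of Gbp1 (4.91), Ndufs5 (4.65), H2-Q2 (4.64), Serpina3h (4.10), C4a (4.04), Fgfbp1 (4.004) and Krtdap (3.12), and Ifi202b had 20.2 FPKM where C57BL/6J was listed at 0. At the other end stood Rps18 (-6.59), Rpl29 (-5.49), Rpl3 (-4.61), Xist (-4.51), the proton pump gene Atp6v0c (-4.13) and Hmgn2 (-3.73), and Rpl35a and Plac9 were listed at 0 in BALB/c with 74.2 and 23.5 FPKM in C57BL/6J. Of 11 genes at least 4-fold lower in both BALB/c libraries than in both C57BL/6J libraries, 8 share their symbol with an annotated pseudogene, and the 28 ribosomal protein genes of the fixed list had a median of 0.03 with 5 lower. Several of the higher genes, such as Gbp1, H2-Q2, Serpina3h and C4a, belong to families of similar sequence.

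Epithelial markers had a median of -0.89 (7 of 16 lower, Tff3 at 1.60 against 11.4 FPKM) and mesothelial markers -1.14, while leukocyte lists were higher in BALB/c: 0.90 for pan-haematopoietic genes, 1.02 for B and plasma cells (5 of 10 higher), 0.70 for T cells, 0.63 for macrophages and 1.07 for neutrophils and mast cells (3 of 4 higher). MHC class II genes had a median of 0.64. Fibroblast markers stood at -0.05, smooth muscle genes at 0.23, collagen genes at -0.21, niche factors at -0.33, complement genes at -0.25 and the unfolded protein response at -0.33. The sex-linked list had a median of 0.77 and a mean of -0.09, since Xist went one way and the Y-linked genes the other. Of 40 lists, 10 medians lay above the middle 95% of random matched lists and 8 below it. Higher and lower genes numbered 56 and 104 with a pseudocount of 5, and 478 and 387 with each library rescaled to a sum of 1000000.

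**Figure D3:**
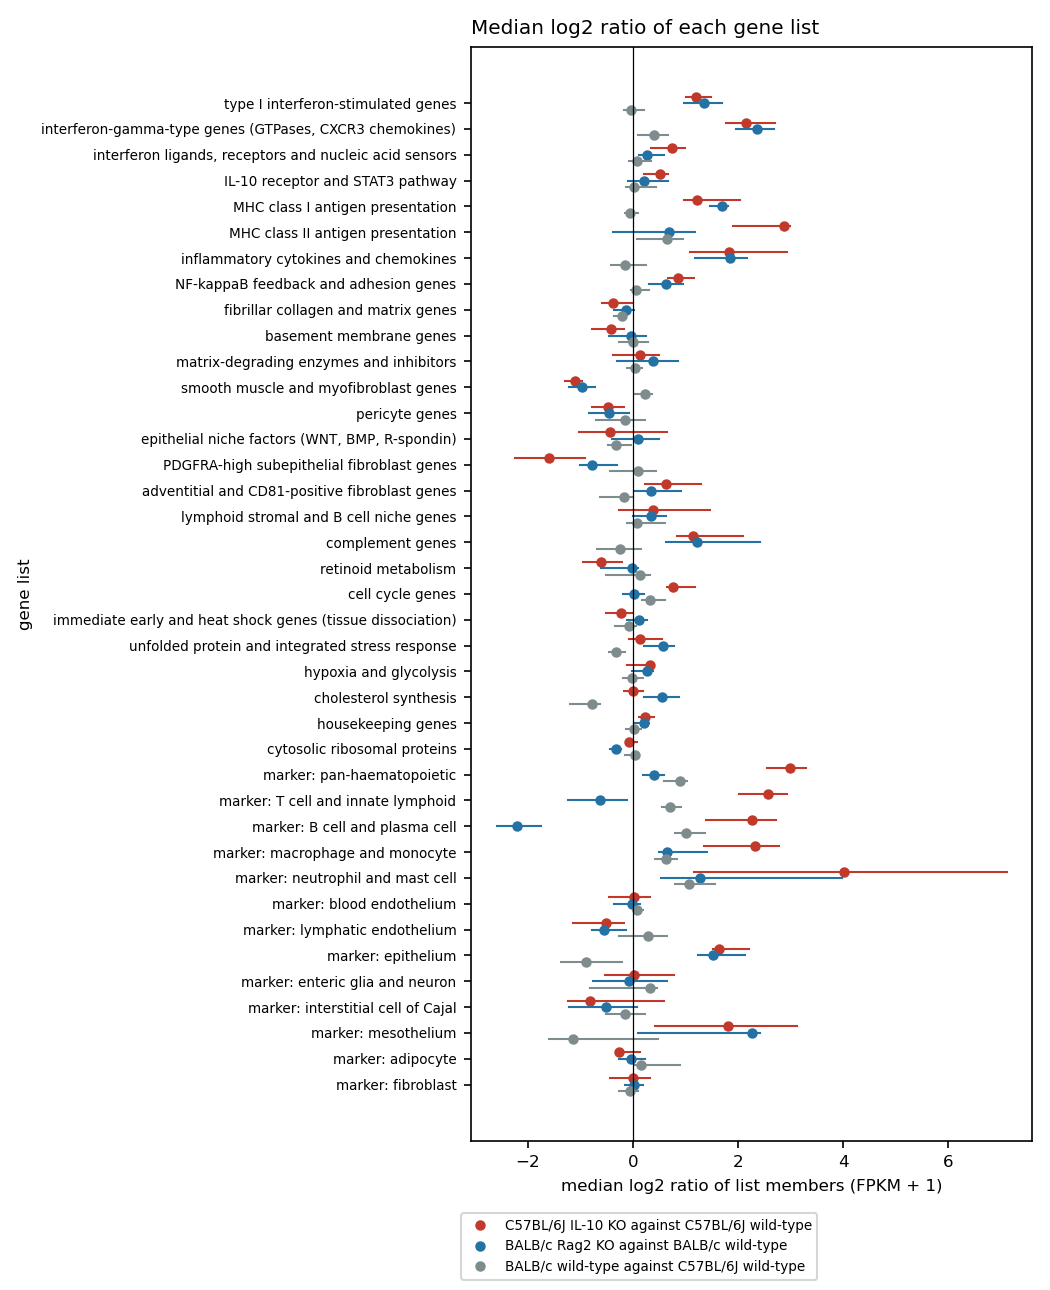
Median log2 ratio of the measured members of each fixed list in the IL-10 comparison (red), the Rag2 comparison (blue) and the comparison of the wild types (grey), with bars for the 95% bootstrap interval over members, which are genes and not replicates. The interferon-gamma-type list lies at 2.15 and 2.36 in the knockout comparisons and at 0.41 between the wild types, and the B and plasma cell list lies at 2.26 in the IL-10 and -2.20 in the Rag2 comparison.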

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

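All tests in this part were chosen after the results were seen, and each library stands for its whole group. The median difference between the knockout log2 ratios was 3.09 for T cell and innate lymphoid markers, which were higher in the IL-10 knockout (2.56) and lower in the Rag2 knockout (-0.62), and this difference was not tested. For B and plasma cell markers it was 4.71, with medians of 2.26 and -2.20 in opposite directions, and it was not tested either.

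The first pattern is the higher level of interferon-induced genes in both knockout libraries, in mice that differ in strain and genotype. A larger share of a cell type cannot raise a transcript by a greater fold than that of markers made by this type alone. In the Rag2 knockout, ratios without a pseudocount exceeded both the pan-haematopoietic and the macrophage median. The margin over the latter was 0.79 for the type I list (interval 0.01 to 1.18) and 1.79 for the interferon-gamma-type list (0.98 to 2.17). This argues against a larger share of leukocytes in an unchanged mix. The mix did change, as B cell markers were lower, so the pan-haematopoietic median sets no bound for a single leukocyte type. Macrophages stay open, since marker transcripts made by stromal cells could lower the macrophage median. Left open too are leukocytes in the IL-10 knockout, with the interferon-gamma-type list -0.71 from the pan-haematopoietic median. The type I median there (1.37) lay below the pan-haematopoietic (3.455) and macrophage (2.455) medians, so such a share could suffice for it. Neutrophils and mast cells in the Rag2 knockout are also open. From their marker median the lists lay -0.0037 (type I) and 0.99 (interferon-gamma-type), with intervals that hold 0. Their 8 markers gained 220 FPKM in sum there against 3317 for the 27 interferon-gamma-type genes. In the IL-10 knockout 10 markers gained 3836 against 2849 for 27 genes, and S100a8 and S100a9 supplied most of the 3836. These gains did not go in parallel, but the sums depend on the number of genes and on how abundant each gene is in its source. The difference of the median gains in the Rag2 knockout (60.04) has an interval of -6.81 to 137. Epithelial cells stay open as well. In the IL-10 knockout the type I and interferon-gamma-type lists lay -0.40 (-1.25 to -0.05) and 0.97 (0.02 to 1.33) from the epithelial median. In the Rag2 knockout they lay -0.66 (-1.21 to -0.09) and 0.34 (-0.16 to 0.89) from it. Marker transcripts made by stromal cells could lower the epithelial median and so produce a positive margin. The interferon-gamma-type genes gained 64.5 FPKM at the median against 6.32 for epithelial markers in the Rag2 knockout (difference 58.1, 26.1 to 137). In the IL-10 knockout they gained 49.5 against 14.8 (34.7, -1.07 to 99.5). The type I genes gained 7.79 against 6.32 in the Rag2 knockout (1.47, -9.26 to 9.12). In the IL-10 knockout their gain was 10.2 against 14.8 (-4.61, -25.3 to 2.58). Gains depend on the levels in epithelium, which were not measured, so they do not decide an epithelial source. The source of these transcripts cannot be told apart, although the gate should remove cells with CD45 or EpCAM (S100a9 reached 121 FPKM in the Rag2 and 1833 in the IL-10 knockout, Tff3 88.6 in the latter), and activated leukocytes, the genotypes themselves, as the biological hypothesis, and, in the IL-10 comparison alone, sex may contribute and were not tested.

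The second pattern is a set of 11 genes, 6 of them ribosomal protein genes, among protein-coding genes at 5 FPKM or more in both C57BL/6J libraries, with values in both BALB/c libraries at least 4-fold below both C57BL/6J libraries. A lower level of ribosomal protein transcripts as a whole is argued against by the fixed list, whose median was 0.031. Reads shared with pseudogene copies are a candidate explanation: 8 of the 11 genes share their symbol with an annotated pseudogene, against 2.98% of 6774 comparable genes and at most 4 in 10000 random matched draws. Near-absent housekeeping genes in all 4 libraries (Gapdh 0.349 FPKM or less) show that low values of abundant genes are not limited to BALB/c. Strain variants that lead reads to another copy may be involved, but no reads were analysed here, and a strain difference in these transcripts themselves stays open and untested.

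The third pattern is Il10, at 129.9 FPKM in the library labelled IL-10 knockout. A larger share of leukocytes as a whole is argued against, since the log2 ratio of Il10 without a pseudocount was 5.28 (4.78 to 5.84) and the highest of 12 pan-haematopoietic markers, Coro1a, was at 3.998. A larger share of T cells, B cells or macrophages beyond that stays open: the upper interval ends of their medians were 4.25 or less, but the single markers Cd247 (5.10) and Fcgr1 (5.07), at 0.246 and 0.144 FPKM in wild type, reached the interval of Il10, and neutrophils and mast cells stay open too, with a marker median of 7.91 over 5 genes and an interval of 3.06 to 11.4, although the gate should remove cells with CD45. Exchanged labels cannot be told apart from correct ones by this gene, since Il10 was at 3.33 FPKM and not near 0 in the library labelled C57BL/6J wild type. An allele that is transcribed but makes no protein may also give such values, and exon-level data, which would show it, were not analysed here.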

How the results depend on the processing

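Counts against both wild types, between all strain pairs, without small RNA rows and by counting interval were chosen after seeing the data, the other alternatives earlier. Counts are given as higher and lower genes per comparison, and where a value crosses 1.5-fold the cause was not tested unless stated. With a pseudocount of 5, which draws all ratios toward 0 by construction, they were 611 and 182 (IL-10), 278 and 68 (Rag2), 56 and 104 (strain) and 393 and 130 (difference), with 199 genes higher and 31 lower in both knockouts. A pseudocount of 0.1 gave 787 lower genes (IL-10), 532 (Rag2), 645 (difference) and 196 in both knockouts, and 477 higher and 452 lower between the strains. Rescaling to a sum of 1000000 raises every FPKM against the pseudocount: 755 (IL-10), 502 (Rag2), 523 (difference) and 176 (both) genes were lower, and 478 higher between the strains. A filter of 5 FPKM, which leaves fewer genes, gave 846 higher genes (IL-10), 159 lower (Rag2), 129 higher (strain) and 593 higher (difference). At 4-fold, stricter by construction, the counts were 478 and 62 (IL-10), 150 and 34 (Rag2) and 41 and 47 (strain). Requiring 2-fold against both wild types left 294 lower genes (IL-10) and 107 (Rag2), and requiring it between all strain pairs left 40 higher and 65 lower.

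The correlation across genes was 0.529 and 0.588 with pseudocounts of 0.1 and 5, 0.526 without a filter, 0.625 at 5 FPKM and 0.527 after rescaling to a common sum. The type I median was 0.88 in both knockout comparisons with a pseudocount of 5 and ranged up to 1.36 (IL-10) and 1.56 (Rag2) over 8 alternatives. The interferon-gamma-type median ranged from 1.73 (pseudocount of 5) to 2.76 (pseudocount of 0.1) in the IL-10 and from 1.99 to 2.53 in the Rag2 comparison. The niche factor median in the IL-10 comparison turned from -0.44 to 0.15 without genes of other lists, which removed the PDGFRA-high genes it shares. The mesothelial median of the difference turned from 0.53 to -0.042 without a filter and to -0.14 at 5 FPKM, and the cause was not tested. Of the other alternatives, the median of ratios, the counting interval and leaving out small RNA rows moved no count by over 1.5 times. Among 1109 alternative list medians 1055 stayed within their interval, 51 moved and 3 reversed. For named genes 2575 of 2808 values stayed and 233 moved, 153 of these toward 0 with a pseudocount of 5. Stayed means a shift no larger than the average reach of the counting interval to either side. Genes without a finite interval were counted as stayed. The count of 0 reversed values was largely fixed in advance. Neither a pseudocount nor these rescalings can turn the sign of a 2-fold ratio between a pair of libraries. Depth limits mainly genes near 1 FPKM, where about 15 fragments leave an interval of 1.13 on either side of a log2 ratio without a pseudocount. The pseudocount of 1 makes that interval narrower.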

Other observations

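The test in this part was chosen after the result was seen. Several genes and groups stood further apart in 1 knockout comparison than in the other. The metalloproteinase inhibitor gene Timp3 had 748 FPKM in the Rag2 knockout against 256 in BALB/c wild type, and 177 in the IL-10 knockout against 248 in C57BL/6J wild type. Igfbp5, which binds insulin-like growth factors, had 689 against 133 FPKM in the Rag2 comparison and 247 against 185 in the IL-10 comparison. Wnt4 had 6.45 against 34.1 FPKM in the IL-10 comparison and 26.0 against 24.98 in the Rag2 comparison, and Pi16 had 502.7 against 75.4 and 133 against 132. Cholesterol synthesis genes had a median log2 ratio of 0.55 in the Rag2 comparison and 0.01 in the IL-10 comparison. BALB/c wild type, the reference of the former, was itself low against C57BL/6J wild type (-0.77).

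Other genes differed in the same direction in both knockouts. Aldh1a1 had ratios of -2.03 (IL-10) and -1.68 (Rag2), the basement membrane collagen gene Col4a5 -2.54 and -1.71, the matrix glycoprotein gene Tnc -1.43 and -1.37, and the pericyte-associated gene Steap4 2.504 and 1.37. The cytokine gene Il22, whose product acts on epithelium, had ratios of 2.75 and 2.70. Between the strains, the urokinase gene Plau had 224 FPKM in BALB/c wild type and 84.6 in C57BL/6J wild type, and 125.5 and 27.3 in the knockouts. H2-Ea-ps, chosen after its values were seen, had 190.9 and 284.6 FPKM in the BALB/c libraries and was listed at 0 in both C57BL/6J libraries.

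In both knockout comparisons the interferon-gamma-type median lay above the type I median. A hypothesis was that the pseudocount compresses the less abundant type I genes. Among members at 5 FPKM or more and without a pseudocount, the medians still differed by 1.32 (interval 0.54 to 1.77) in the IL-10 and by 1.01 (0.57 to 1.54) in the Rag2 comparison, which argues against it. Between the wild types the difference was 0.50 (-0.02 to 0.77). Whether interferon-gamma or another signal raises the first list may be asked of other data, since the members of both lists respond to more than 1 interferon and no test here separates them.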
